A study of Homo sapiens with 14 samples.

How the data were processed

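Total RNA of 14 neuroblastoma cell lines was isolated with TRIzol and made into TruSeq libraries, per the labels' protocols, with 1 library per line. The lines are established cultures grown in standard medium. The submitters' processing notes name kallisto 0.44.0, DESeq2 1.48.2 and the genome build GRCh38, without saying which step each served. The annotation, the way transcripts were summed into genes, the strand setting and any filter are not given in the sources used here.

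The deposited table of estimated counts per gene holds whole numbers for 20049 gene symbols. As kallisto, named in the submitters' processing notes, estimates counts, the values deposited by the authors were read in the unit of expected counts (estimates), rounded to whole numbers, with no scaling between libraries. This unit rests on the values themselves, since no source states it. The deposited table of log2 values is called variance-stabilised in its name, and its settings are not stated. At high counts it followed the log2 count up to a shift per library and a smaller shift per gene and library that no source explains, and it was used only as an alternative scale. Library totals ran from 35856642 counts (Lan-6) to 58644013 counts (LS). A count of 0 allows up to 3 counts, which is 0.0514 CPM in LS, the deepest library, and 0.102 CPM in Lan-6, where the scaled library was smallest. Intervals and such limits cover counting error only. Mitochondrial genes took 3.44% (LS) to 11.7% (IMR5-75) of counts. No pair of the 91 pairs of libraries held the same counts, and the smallest chi-square per gene between any pair was 273, so no library was counted as a copy of another.

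From the counts, CPM and log2 CPM with a prior count of 2 were computed with TMM factors in edgeR 4.0.16 (R 4.3.3). Genes with at least 1 CPM in at least 3 lines were tested, 15674 over the 12 lines of separate donors and 15919 over all 14. That SH-SY5Y comes from SK-N-SH and IMR5-75 from IMR32 is textbook knowledge and is not in the labels. The labels give 1 group and no replicates, so p-values measure the spread between lines, including any technical difference between single libraries. Before the data were examined, 18 gene lists, 12 relations, the scans, the alternatives and the rule for named genes were fixed. The lists were antigen presentation, interferon-stimulated genes, nucleic acid sensing, mesenchymal and adrenergic markers, telomerase components, shelterin, genes linked to telomerase-independent lengthening, MYC-responsive genes, checkpoint and surface ligands, natural killer cell receptor ligands, DNA damage response, proliferation, drivers, and markers of leukocytes, endothelium, Schwann cells and fibroblasts. Of 191 memberships, all but that of TERC, which was not analysed here, were measured. Older symbols were matched to current ones, such as TMEM173 for STING1 and DDX58 for RIGI. Positions are from GENCODE 29 on GRCh38, in which 98.7% of the symbols matched 1 gene.

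Each relation was tested by Pearson's r and Spearman's rho over 12 lines with 2-sided permutation tests of 100000 resamples (scipy 1.17.1), adjusted by Benjamini-Hochberg over the 12 relations, and repeated without the 2 lines farthest from the median of the first measure. A measure would have been split had its largest gap between neighbouring lines, with at least 3 lines on each side, been over 0.4 of its range, and none was, the widest gap being 0.311. Each scan fitted a slope on 1 level (the antigen presentation score, TERT or MYCN, in SDs) with edgeR's quasi-likelihood test and an adjusted p threshold of 0.05, leaving out the genes that make up the level. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one. The rule for named genes took list members, and per scan the 15 steepest rising and 10 steepest falling called genes with a mean of at least 5 CPM whose unadjusted p stayed under 0.05 without the 2 farthest lines, and per line up to 3 genes with the highest ratio to the next line. XIST and Y-linked genes were left out, and the results of some genes are not reported.

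The scans were tested on simulated counts for 15641 genes with 200 genes given known slopes. A slope of 2 log2 per SD was recovered in 84% of genes for MYCN, 80% for antigen presentation and 70% for TERT. A slope of 1 was recovered in 24%, 18% and 6%, a slope of -1 in 36%, 14% and 16%, and a slope of 0.5 in 0%, 0% and 2%. Of genes with no slope, 0%, 0.0130% and 0.0259% were called. The simulated genes were drawn independently of each other, so these shares do not cover genes that move together across lines. In 200 simulated relations over 12 lines, a true r of 0.6 gave an unadjusted permutation p under 0.05 in 53.5% of sets and a true r of 0.9 in 99.5%, against 7% with none.

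The alternatives were DESeq2's size factors, DESeq2 1.42.0 in place of edgeR, limma on the deposited log2 values, no filter, a prior count of 0.5, z-scores, all 14 lines, subclones in place of their parents, each line left out, and other thresholds and measures for line-specific genes and kinship. Chosen after seeing the data were the antigen presentation list without HLA genes, the omission of Lan-6 and GI-ME-N, removal of the GC and length trend, and the mesenchymal score as a covariate. For the trend, each library's deviation from the 14-line median was smoothed over 20 bins of GC content and of length of the longest transcript, which 99.2% of tested genes and all 188 list genes had. The share of variance it took was measured on the 3949 genes most stable over 6 lines, with 6 other lines as reference. This replaced a first version in which the stable genes had been picked on the reference lines themselves. Runs of neighbouring genes were at least 4 consecutive genes, among 10183 with a median of at least 10 CPM, that were each at least 4-fold over their 14-line median in a line. That definition was the third tried, after windows of 7 and of 3 genes, and was chosen after seeing the data. For each scan 40 random orders of the level over the lines were drawn.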

Results

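RNA from 14 human neuroblastoma cell lines was sequenced, with 1 library per line. Neuroblastoma is a childhood tumour of the sympathetic nervous system. The lines were SK-N-BE(2)C, CLB-GA, GI-ME-N, IMR32, IMR5-75, Lan-6, LS, NBL-S, NGP, SK-N-AS, SK-N-DZ, SK-N-FI, SK-N-SH and SH-SY5Y. The series concerns telomere damage, immunogenicity and the response to antibodies against PD-L1. The labels set no line apart from the others by treatment or class, so levels are given per line, and relations between levels were tested across lines. Library totals ranged from 35856642 counts in Lan-6 to 58644013 in LS, over 20049 gene symbols. There are no replicates of any line, and limits given for single values cover counting error only, so a difference between 2 lines has no replicate check. SH-SY5Y was derived from SK-N-SH and IMR5-75 from IMR32. The tests across lines therefore used the 12 other lines, 1 per donor. Levels are CPM, counts scaled to a common library total. A list score is the mean log2 CPM of the detected members of a gene list, each centred on its mean over the 14 lines.

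The first question was how the lines differ in genes of telomere maintenance. TERT, the catalytic subunit of telomerase, was highest in GI-ME-N at 68.5 CPM. It followed at 25.1 CPM in CLB-GA, 20.6 in NGP, 19.3 in NBL-S and 17.4 in SH-SY5Y. IMR5-75, SK-N-SH, LS, IMR32 and SK-N-DZ held between 4.72 and 7.33 CPM. TERT stood at 0.921 CPM in SK-N-AS and 0.728 CPM in SK-N-BE(2)C. Lan-6 had 2 TERT counts, or 0.0678 CPM, and SK-N-FI had 0, which allows a level of up to 0.0542 CPM (3 counts). ATRX, a chromatin remodeller whose loss is known from tumours that lengthen telomeres without telomerase, was detected in every line, from 41.0 CPM in Lan-6 and 60.2 CPM in GI-ME-N to 235 CPM in SH-SY5Y. Both low values came from libraries in which long and AT-rich transcripts were low, and with that trend removed ATRX was at 112 CPM in Lan-6 and 111 CPM in GI-ME-N. DAXX ranged from 46.6 CPM in IMR5-75 to 252 CPM in Lan-6, or 162 CPM there with the trend removed. The other 6 genes linked to telomerase-independent lengthening were detected in all 14 lines, and the score of the 8 ranged only from -0.47 in SK-N-SH to 0.23 in SK-N-DZ.

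All 7 measured telomerase components were above their own 14-line median in GI-ME-N, whose score for this list was 1.46 against -1.02 in SK-N-FI, the lowest. GI-ME-N held the highest level of 4 of the components and Lan-6 of 2. In both libraries long transcripts were low (rho with length -0.396 in GI-ME-N and -0.466 in Lan-6 over stable genes). The levels of these components still hold that trend. DKC1 had a median of 124 CPM and NHP2 a median of 95.3 CPM. The score of the 6 shelterin genes, whose products cap telomeres, had the lowest SD of all lists, 0.223. That of the genes linked to telomerase-independent lengthening was close, at 0.231. A score averages its members, so opposite moves of single members cancel in it. TERF1 lay between 21.0 CPM (Lan-6) and 48.7 CPM (SK-N-AS), and POT1 between 16.2 CPM (NBL-S) and 44.6 CPM (NGP). With the GC and length trend removed TERF1 was at 38.9 CPM in Lan-6 and lowest in IMR5-75 at 29.9 CPM, and POT1 was highest in GI-ME-N at 51.6 CPM. ACD stood out in Lan-6 at 130 CPM, which became 48.0 CPM with the GC and length trend of that library removed.

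**Figure D1:**
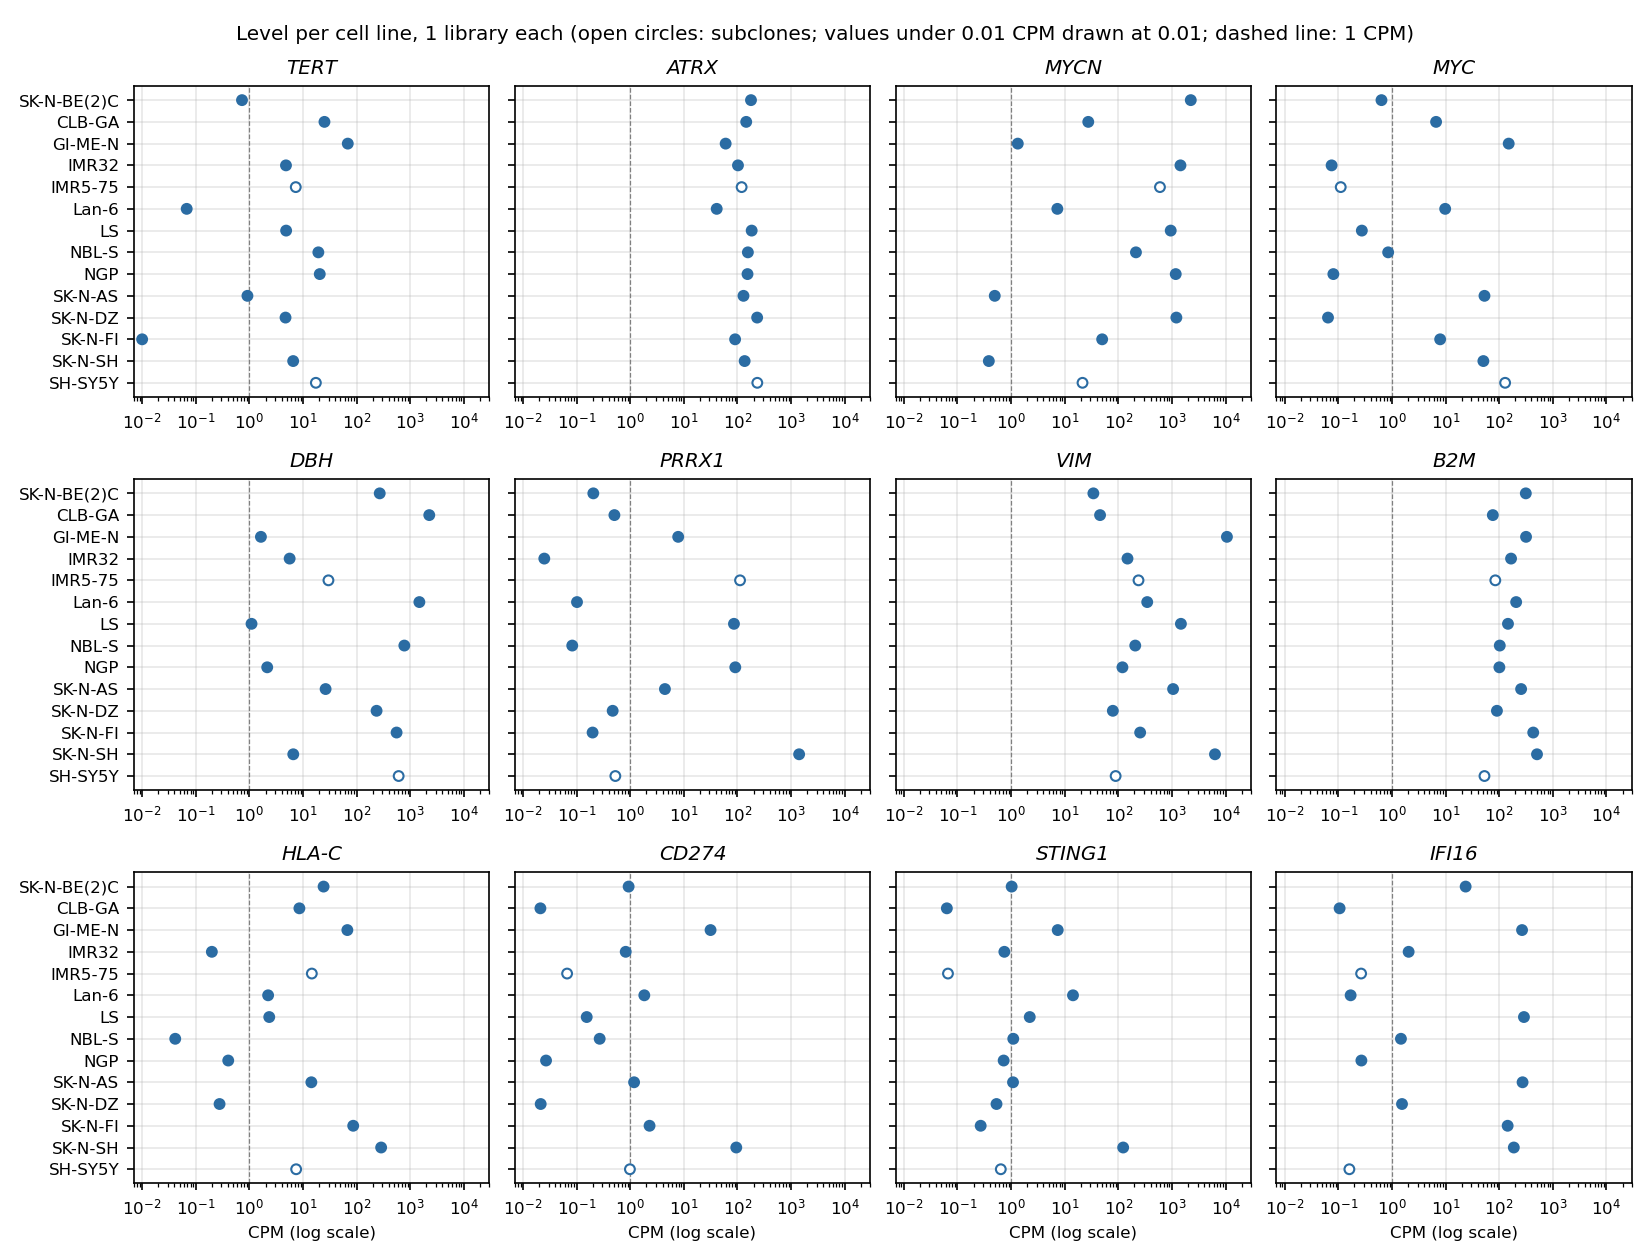
Level of 12 genes in each of the 14 lines, as CPM on a logarithmic axis, 1 library per line, with open circles for the subclones. TERT ran from 0 in SK-N-FI to 68.5 CPM in GI-ME-N, and MYCN from 0.384 CPM in SK-N-SH to 2245 CPM in SK-N-BE(2)C.

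Among known drivers, MYCN, a transcription factor amplified in many aggressive neuroblastomas, was at 2245 CPM in SK-N-BE(2)C, 1442 in IMR32, 1209 in SK-N-DZ, 1177 in NGP, 949 in LS and 598 in IMR5-75. NBL-S held 213 CPM and SK-N-FI 49.95 CPM, while GI-ME-N (1.33 CPM), SK-N-AS (0.496 CPM) and SK-N-SH (0.384 CPM) had the least. MYC, its paralog, showed the opposite order: 150 CPM in GI-ME-N, 129 in SH-SY5Y, 53.2 in SK-N-AS and 50.7 in SK-N-SH, and under 1 CPM in all 7 lines with MYCN above 200 CPM. MDM2, the negative regulator of p53, reached 4090 CPM in LS and 922 CPM in NGP against a 14-line median of 120 CPM. CDK4, a cell cycle kinase, reached 1206 CPM in LS and 1608 CPM in NGP against a median of 245 CPM. ALK, a receptor tyrosine kinase, ranged from 0.192 CPM in SK-N-SH to 262 CPM in SH-SY5Y and 258 CPM in CLB-GA. LIN28B, a repressor of let-7 microRNAs, was at 0.142 CPM in SK-N-AS and 132 CPM in NBL-S. NF1, a negative regulator of RAS, was at 3.66 CPM in GI-ME-N (6.13 CPM with the trend removed) and at 43.0 CPM or more in the other 13 lines. Of the 12 MYC-responsive genes, with the trend left in, 11 were above their own median in GI-ME-N and 11 in LS. LDHA, a lactate dehydrogenase subunit, was at 9.81 CPM in SK-N-BE(2)C and between 209 and 3658 CPM elsewhere.

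The lines also differed in the markers of the adrenergic (sympathetic neuroblast) and mesenchymal cell states. SK-N-SH and GI-ME-N had the highest mesenchymal scores, 5.09 and 4.21, and the lowest adrenergic scores, -2.92 and -3.16. VIM, an intermediate filament of mesenchymal cells, was at 10610 CPM in GI-ME-N and 6349 CPM in SK-N-SH, against 34.2 CPM in SK-N-BE(2)C. FN1 (fibronectin) reached 17720 CPM in GI-ME-N, and PRRX1, a mesenchymal transcription factor, 1413 CPM in SK-N-SH. LS came next with a mesenchymal score of 1.80, with YAP1 at 88.3 CPM and PRRX1 at 86.0 CPM. PRRX1 does not single out LS, as it was at 112 CPM in IMR5-75 (mesenchymal score -0.03) and had 3387 counts in NGP (score -1.14). CLB-GA had the highest adrenergic score, 2.29, with 2267 CPM of DBH, the enzyme that makes noradrenaline. The fibroblast markers followed the mesenchymal ones in SK-N-SH (score 4.15) and GI-ME-N (4.05), but SK-N-AS (2.82) came before LS (1.08). COL1A1 was at 9100 CPM in GI-ME-N and 8734 CPM in SK-N-SH, and COL3A1 at 5349 CPM in SK-N-SH and 1216 CPM in SK-N-AS. Cultured mesenchymal-state cells and fibroblasts share these collagens.

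Genes of MHC class I antigen presentation were highest in SK-N-SH (score 3.07) and SK-N-FI (2.32), followed by GI-ME-N (1.21) and SK-N-AS (1.17), and lowest in CLB-GA (-2.15) and NBL-S (-1.94). B2M, the invariant light chain of class I molecules, ranged from 53.1 CPM in SH-SY5Y to 507 CPM in SK-N-SH. HLA-C was at 287 CPM in SK-N-SH and 0.0414 CPM in NBL-S. HLA genes vary between donors and resemble each other, so how reads were assigned to them is uncertain. TAP1, which carries peptides into the endoplasmic reticulum, was at 44.1 CPM in SK-N-SH, 17.3 CPM in SK-N-FI and at most 4.86 CPM elsewhere. PSMB8, an immunoproteasome subunit, had 0 counts in CLB-GA, IMR32, IMR5-75 and NBL-S, and 23.2 CPM in SK-N-SH.

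Interferon-stimulated genes were highest in SK-N-FI (score 1.91), where 18 of 19 detected members were above their own median, followed by SK-N-AS (1.09) and SK-N-SH (0.93). IFI6 was at 122 CPM and MX2 at 100 CPM in SK-N-FI, IFI44 at 88.2 CPM and USP18 at 32.5 CPM in SK-N-AS, and OAS1 at 81.9 CPM in Lan-6. CXCL10 had 5 counts in SK-N-AS and 0 in the other 13 lines. Of the nucleic acid sensors, CGAS, which senses cytosolic DNA, was under 1 CPM in all 14 lines. STING1, which acts downstream of it, was at 123 CPM in SK-N-SH, 14.3 CPM in Lan-6 (6.74 CPM with the trend removed), 7.41 CPM in GI-ME-N and at most 2.23 CPM elsewhere. IFI16, another DNA sensor, was at 290 CPM in LS, 273 in SK-N-AS, 267 in GI-ME-N, 187 in SK-N-SH and 144 in SK-N-FI, and at 0.106 to 23.7 CPM in the others.

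CD274, which encodes PD-L1, was at 95.0 CPM in SK-N-SH and 31.5 CPM in GI-ME-N, and at most 2.29 CPM (SK-N-FI) in the other 12 lines, or 2.90 CPM (Lan-6) with the GC and length trend removed. PDCD1LG2, which encodes PD-L2, was at 23.6 CPM and 17.3 CPM in those lines and at most 0.0918 CPM elsewhere. CD276 (B7-H3) and CD47 were present in all 14 lines, with medians of 113 and 121 CPM. B4GALNT1 and ST8SIA1, enzymes of ganglioside synthesis, were highest in LS (491 CPM) and SK-N-DZ (80.3 CPM), and the latter was at 0.933 CPM in SK-N-SH. In LS, B4GALNT1 lay in a run of neighbouring genes on chromosome 12 that were all raised. Among ligands of natural killer cell receptors, MICA was at 34.6 CPM in GI-ME-N and 24.1 CPM in SK-N-SH and at most 2.58 CPM elsewhere, while ULBP1 was highest in IMR5-75 at 40.2 CPM.

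**Figure D2:**
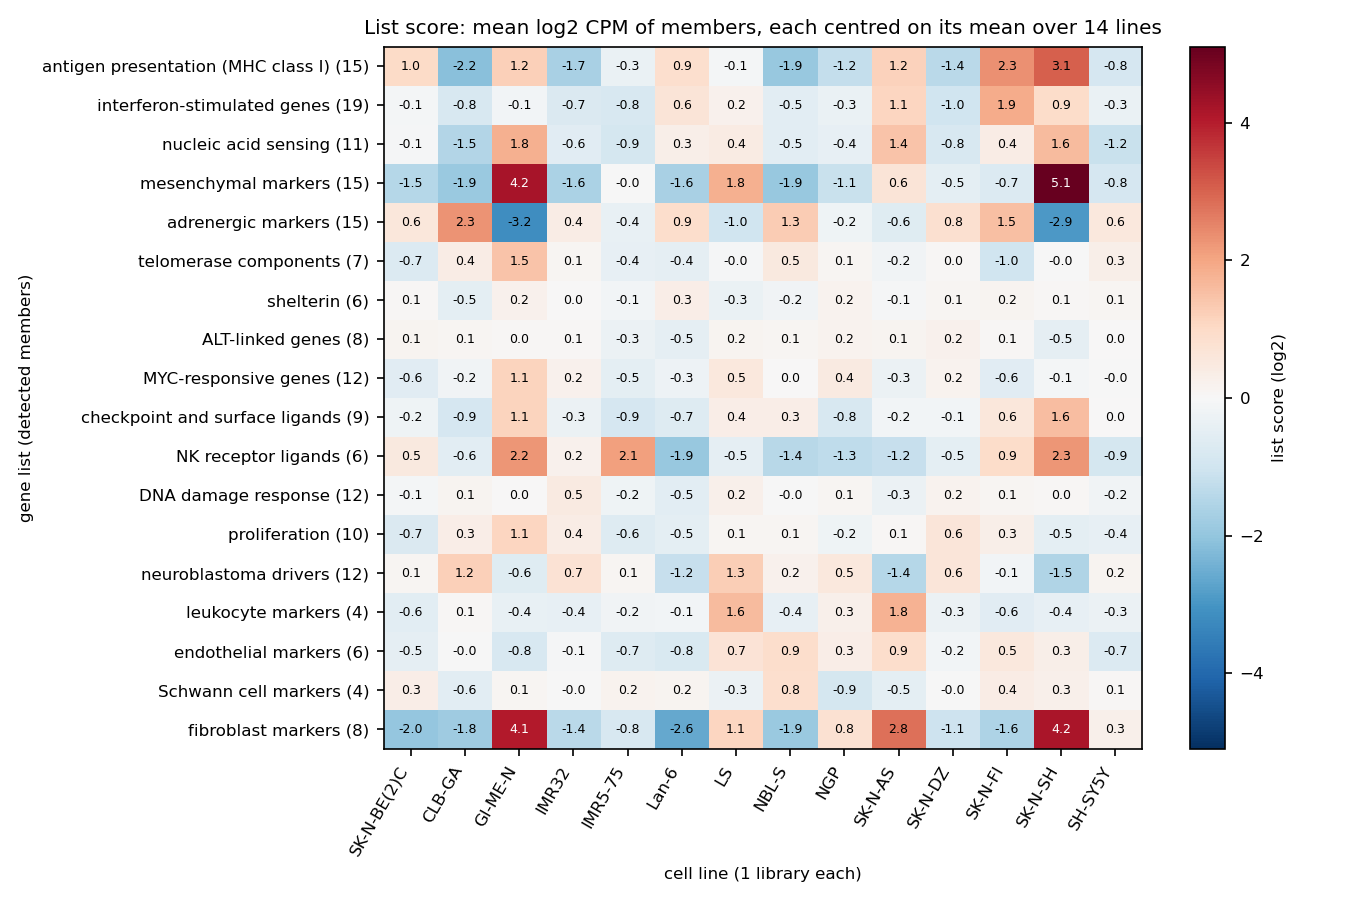
Scores of the 18 gene lists (vertical axis, with detected members) in the 14 lines (horizontal axis, 1 library each), as mean log2 CPM of the members centred on their mean over the lines. SK-N-SH and GI-ME-N had the highest mesenchymal scores (5.09 and 4.21) and the lowest adrenergic scores.

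All 12 DNA damage response genes and all 10 proliferation genes were above 1 CPM in every line. CDKN1A, the p53-induced cell cycle inhibitor, ranged from 8.91 CPM in LS to 981 CPM in SK-N-SH. Proliferation scores ran from -0.72 in SK-N-BE(2)C to 1.09 in GI-ME-N, with the GC and length trend left in. Of 8 leukocyte markers, 4 passed the detection limit. PTPRC, which encodes CD45, was at 470 CPM in SK-N-AS and at most 2.91 CPM elsewhere, and in SK-N-AS CD3E had 0 counts and CD14 was at 0.189 CPM. LYZ was at 42.1 CPM in LS and under 1 CPM elsewhere, and it lies within a run of genes on chromosome 12 that were raised in LS. The endothelial list had its highest score in NBL-S (0.90), with KDR at 3.998 CPM there, and of the Schwann cell markers 4 of 6 were detected, none above 13.5 CPM (ERBB3 in NBL-S).

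In 12 relations fixed in advance, levels were compared across the 12 lines, with 2-sided permutation tests and Benjamini-Hochberg adjustment over the 12. 7 had an adjusted permutation p under 0.05. MYCN and MYC were inversely related, with r = -0.950 (permutation p = 6.0e-05, adjusted p = 7.2e-04) and rho = -0.888 (permutation p = 3.0e-04), and r = -0.949 without SK-N-AS and SK-N-SH, the 2 lines farthest from the median of MYCN. The adrenergic score fell as the mesenchymal score rose, with r = -0.925 (permutation p = 1.3e-04, adjusted p = 7.8e-04), rho = -0.804 (permutation p = 0.00253), and r = -0.743 without GI-ME-N and SK-N-SH. Interferon-stimulated genes and antigen presentation went together, with r = 0.849 (permutation p = 5.5e-04, adjusted p = 0.00220), rho = 0.832 (permutation p = 0.00152), and r = 0.868 without SK-N-AS and SK-N-FI. CD274 and antigen presentation also went together, with r = 0.814 (permutation p = 9.6e-04, adjusted p = 0.00288), rho = 0.867 (permutation p = 4.8e-04), and r = 0.765 without GI-ME-N and SK-N-SH. Nucleic acid sensing and interferon-stimulated genes had r = 0.649 (permutation p = 0.0225, adjusted p = 0.0495), rho = 0.783 (permutation p = 0.00388), and r = 0.782 without CLB-GA and GI-ME-N.

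Mesenchymal markers and antigen presentation had r = 0.628 (permutation p = 0.0281, adjusted p = 0.0495) and rho = 0.727 (permutation p = 0.00968). Its r rested on GI-ME-N and SK-N-SH, without which r was 0.349 (permutation p = 0.331) and rho 0.576 (permutation p = 0.0877). STING1 and antigen presentation had r = 0.620 (permutation p = 0.0289, adjusted p = 0.0495) and rho = 0.455 (permutation p = 0.138). Without both Lan-6 and SK-N-SH r was 0.342 (permutation p = 0.345) and rho 0.285 (permutation p = 0.427), while without Lan-6 alone r was at least 0.617. The relations with adjusted permutation p = 0.0495 are at the threshold. Leaving out any 1 of CLB-GA, IMR32, NBL-S, NGP, SK-N-AS, SK-N-DZ or SK-N-SH ended all 3 (r from 0.3999 to 0.646), leaving out Lan-6 or LS ended those of sensing and STING1 (r from 0.617 to 0.654), and leaving out GI-ME-N ended that of STING1 (r = 0.6005).

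The other 5 relations did not pass. MYCN and antigen presentation had r = -0.607 (permutation p = 0.0395, adjusted p = 0.0593), rho = -0.503 (permutation p = 0.0999), and r = -0.393 without SK-N-AS and SK-N-SH. Leaving out SK-N-BE(2)C, CLB-GA or SK-N-FI took that relation past the threshold, with r = -0.716, -0.700 and -0.653. TERT and antigen presentation had r = -0.496 (permutation p = 0.102, adjusted p = 0.136), rho = -0.329 (permutation p = 0.301), and r = -0.302 without Lan-6 and SK-N-FI. Without GI-ME-N r was -0.658 with an adjusted permutation p of 0.0485. TERT and ATRX had r = 0.316 (permutation p = 0.317, adjusted p = 0.380) and rho = 0.133 (permutation p = 0.683), and r turned to -0.468 without Lan-6 and SK-N-FI and to -0.0269 without Lan-6 alone. TERT and nucleic acid sensing had r = -0.115 (permutation p = 0.721, adjusted p = 0.787), rho = -0.0490 (permutation p = 0.885), and r = -0.0830 without Lan-6 and SK-N-FI. MYCN and TERT had r = 0.0385 (permutation p = 0.905, adjusted p = 0.905), rho = -0.175 (permutation p = 0.591), and r = -5.6e-04 without SK-N-AS and SK-N-SH. Values this close to 0 also changed sign in single omissions, to -0.0709 without Lan-6, -0.0381 without NGP and -0.0488 without SK-N-AS for MYCN and TERT, and to 0.0362 without CLB-GA for TERT and sensing.

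**Figure D3:**
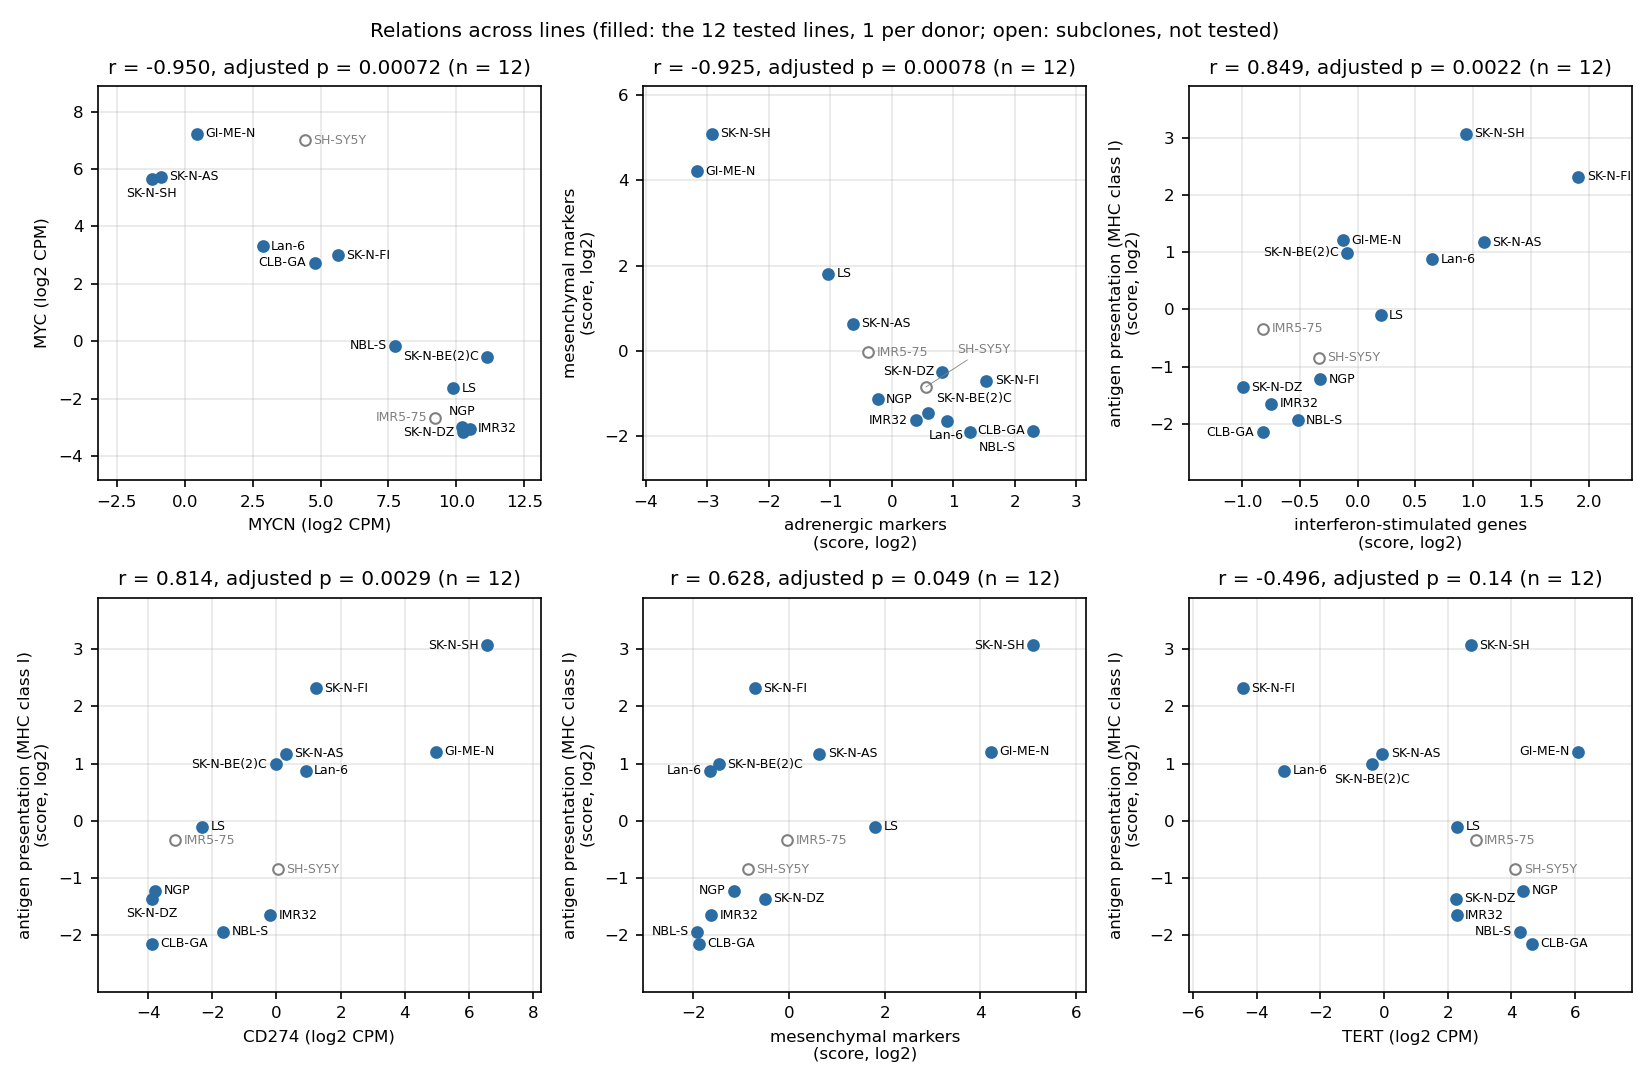
Relations across lines for 6 pairs of measures, as log2 CPM for genes and list scores in log2 units, with the 12 tested lines filled and the subclones open. MYCN and MYC had r = -0.950, and TERT and antigen presentation r = -0.496 with an adjusted permutation p of 0.136.

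To ask which genes followed antigen presentation across the 12 lines, each of 15626 genes outside the list was tested for a slope on the score, given as log2 per SD of the score. STOM, a membrane scaffold protein at chromosome 9:121338988-121370304 (GRCh38), rose with the score, with a slope of 3.33 (SE 0.50), from 0.649 CPM in IMR32 to 522 CPM in SK-N-FI. DDX60L, a relative of the antiviral helicase DDX60, at 4:168356735-168537786, rose with a slope of 2.09 (SE 0.31), from 1.08 CPM in CLB-GA to 38.5 CPM in SK-N-AS. GRM8, a glutamate receptor at 7:126438598-127253294, fell with a slope of -2.93 (SE 0.40), and SLC1A2, a glutamate transporter at 11:35251205-35420063, with a slope of -2.61 (SE 0.37). HMGCS1, an enzyme of cholesterol synthesis at 5:43289395-43313512, fell with a slope of -1.04 (SE 0.16), from 438 CPM in IMR32 to 34.8 CPM in SK-N-SH. The sixth called gene, KCTD8, an auxiliary subunit of GABA-B receptors, fell with a slope of -4.75 (SE 0.60), and was chosen after its values were seen, as its mean of 3.63 CPM lay outside the rule for named genes. The adjusted p in edgeR's quasi-likelihood test lay between 0.0449 (KCTD8) and 0.0481 (STOM and DDX60L), and 2108 genes had an unadjusted p under 0.05.

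As groups, 18 of 19 interferon-stimulated genes and 10 of 11 nucleic acid sensing genes had positive slopes on the antigen presentation score. Adjusted over the list alone, 7 interferon-stimulated genes rose, among them IFI6 (slope 1.85, SE 0.49) and IFIT2 (0.97, SE 0.22), and 3 sensing genes rose, STING1 (2.38, SE 0.48), IFIH1 (4.54, SE 1.12) and RIGI (0.68, SE 0.21), while 0 of either passed over all genes. In camera with a preset correlation the adjusted p was 3.8e-06 and 4.1e-04 for these lists, and 0.0216 for both with an estimated correlation. All 15 mesenchymal markers and all 8 fibroblast markers had positive slopes, and adjusted over the list alone 8 and 6 rose, including VIM (2.28, SE 0.68), FOSL1 (4.10, SE 1.18) and COL3A1 (3.31, SE 0.91). Their camera adjusted p was 5.9e-08 and 4.1e-04, and 0.175 for both with an estimated correlation. All 15 adrenergic markers had negative slopes, 0 past the test adjusted over the list alone (camera adjusted p = 0.00168, and 0.242 with an estimated correlation). Of 5 tested natural killer cell ligands, MICA (1.36, SE 0.47) and MICB (1.21, SE 0.30) rose adjusted over the list alone (camera adjusted p = 0.00559, and 0.175 with an estimated correlation). Among checkpoint and surface ligands CD274 rose (2.99, SE 0.64) and ST8SIA1 fell (-1.73, SE 0.44), and among drivers BRIP1 fell (-0.65, SE 0.18), all adjusted over the list alone. The driver list had a camera adjusted p of 0.00559, and 0.175 with an estimated correlation. EMCN of 3 endothelial genes rose (0.67, SE 0.22) adjusted over the list alone, as did CD68 (0.99, SE 0.32) and PTPRC (3.21, SE 1.38), the only leukocyte markers tested. PTPRC was high in SK-N-AS alone, with 19896 counts there against 18 to 128 in the other 13 lines. The other lists gave camera adjusted p of 0.282 or more.

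The 6 calls were close to the threshold. edgeR called 0 genes when SK-N-BE(2)C, CLB-GA, IMR32, Lan-6, LS, NGP, SK-N-DZ or SK-N-SH was left out. The number was 1 without SK-N-AS, 5 without NBL-S, 12 without GI-ME-N and 14 without SK-N-FI. All 6 genes kept their sign and an unadjusted p under 0.05 in each of these 12 omissions. They had been called on nearly the same lines at a stricter threshold, so this is no independent support. edgeR also called 0 with the GC and length trend removed, and DESeq2 called 1012. With the score taken without HLA genes edgeR called 5, all falling and 4 of them among the 6, so STOM and DDX60L were not called there.

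TERT gave no such genes. Of 15640 genes tested for a slope on TERT across the 12 lines, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05, 1077 had an unadjusted p under 0.05, and DESeq2 called 297. Interferon-stimulated genes had negative slopes in 17 of 19 cases, and adjusted over the list alone IFI6 (-1.57), IFI27 (-1.16) and OAS1 (-2.10) fell, with a camera adjusted p of 1.7e-07, and 0.0791 with an estimated correlation. SK-N-FI and Lan-6, the lines farthest from the median of TERT, held the highest counts of IFI6 (6749 and 1372), IFI27 (1970 and 526) and OAS1 (1248 and 2417). The slopes of IFI6, IFI27 and OAS1 may therefore rest on those lines. ENPP1 (1.94) of the sensing list and COL1A2 (3.47) of the fibroblast list rose adjusted over the list alone. COL1A2 was at 1872 CPM in GI-ME-N, the line with the most TERT, and at 24.4 CPM in SK-N-SH, the next. Antigen presentation genes had negative slopes in 14 of 15 cases (camera adjusted p = 2.5e-05, and 0.584 with an estimated correlation), and all 12 MYC-responsive genes had positive slopes (camera adjusted p = 2.1e-05, and 0.183 with an estimated correlation). All 15 mesenchymal markers (camera adjusted p = 6.9e-04) and 9 of 10 proliferation genes (camera adjusted p = 0.0171) had positive slopes, as had 5 of 8 fibroblast markers (camera adjusted p = 0.0312), and the adjusted p was 0.584 for each with an estimated correlation. The other lists had camera adjusted p of 0.0522 or more. Without CLB-GA edgeR called 2 genes.

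MYCN gave the largest set, with 554 of 15640 genes called across the 12 lines by edgeR's quasi-likelihood test at an adjusted p under 0.05, 182 rising and 372 falling with MYCN. The excess of falling genes was not found with limma on the deposited stabilised values, with 220 rising and 218 falling, and DESeq2 called 1186 rising and 1488 falling. NHLH2, a neuronal transcription factor at 1:115836377-115843917, had a slope of 5.03 log2 per SD (SE 1.19, adjusted p = 0.0410) and reached 113 CPM in IMR32. CACNA1H, a T-type calcium channel at 16:1153121-1221772, had a slope of 4.93 (SE 0.82, adjusted p = 0.0245), from 0.0236 CPM in SK-N-AS to 104 CPM in NGP. POU4F1, a sensory neuron transcription factor, had a slope of 3.59, and DSCAM, a neuronal adhesion protein, a slope of 4.41. The others of the 15 named by the rule were TMEM271, ANOS1, THSD7B, PARM1, LGI2, NXPH1, ADAMTS20, ZDHHC22, FUT9, NELL1 and PAX5, with slopes from 3.19 to 4.46.

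Among the falling genes, TGFBI, a matrix protein induced by TGF-beta, at 5:136028895-136063818, fell with a slope of -4.91 (SE 0.81, adjusted p = 0.0245 in edgeR), from 3563 CPM in SK-N-SH. CAVIN1, a component of caveolae, had a slope of -4.35, and TGM2, a transglutaminase, of -3.62. MYC itself fell with a slope of -3.56 (SE 0.45, adjusted p = 0.0161 in edgeR), at 8:127735434-127741434. Others were S100A16, KRT18, COL1A2, FXYD5 and HSPB6, with slopes from -3.74 to -4.09. GI-ME-N or SK-N-SH, which had the highest mesenchymal scores, held the highest level among the 12 lines of each of these genes.

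By list, all 15 mesenchymal markers had negative slopes on MYCN, of which FOSL1 (-4.22, SE 0.61) fell over all genes and 10 adjusted over the list alone (camera adjusted p = 6.7e-06). All 8 fibroblast markers had negative slopes, of which COL1A2 and LUM fell over all genes and 5 adjusted over the list alone (camera adjusted p = 0.00304). Of 11 sensing genes, IFIH1 (-3.56, SE 0.62) and STING1 (-2.23, SE 0.52) fell over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0109). All 15 antigen presentation genes had negative slopes, 0 past the test over all genes and 2 falling adjusted over the list alone (camera adjusted p = 1.6e-04). With an estimated correlation the adjusted p was 0.517 for each of these 4 lists. CD274 fell (-2.64, SE 0.62) and ST8SIA1 rose (1.86, SE 0.41), and GAR1, a telomerase component, fell (-0.51, SE 0.13), as did CD68 (-1.28, SE 0.22), all over all genes. Of 12 MYC-responsive genes 7 had positive slopes and 1 rose adjusted over the list alone (camera adjusted p = 0.726), and no other list had a camera adjusted p under 0.0579.

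The number of MYCN calls moved with single lines and with the method. edgeR called 0 genes with subclones in place of their parents (3395 at an unadjusted p under 0.05), and DESeq2 called 2674 over the 12 lines. In edgeR the number was 287 without SK-N-BE(2)C, 7 without GI-ME-N, 0 without IMR32, 859 without Lan-6, 298 without LS, 117 without NBL-S, 3 without NGP, 1296 without SK-N-AS, 41 without SK-N-DZ and 5 without SK-N-SH, while 508 of the 554 genes kept their sign and an unadjusted p under 0.05 in edgeR in every omission of 1 line. With the mesenchymal score as a covariate 1 gene was called, 471 of the 554 kept their sign and an unadjusted p under 0.05, and the slope of COL1A2 was 0.085. The 554 genes had been called on these lines at a stricter threshold, so neither number of kept genes is independent support.

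Each line was also searched for genes at 10 CPM or more there and at least 8 times the level of the next line, as a description with no test. There were 240 such genes, 70 in SK-N-SH, 36 in GI-ME-N, 20 in SK-N-FI, 19 in SK-N-AS and 17 in LS, and 1 in IMR32. SK-N-SH led in SUCNR1, the succinate receptor, at 113 CPM against 0.253 CPM in SK-N-FI, and in FBLN5, an elastic fibre protein, at 166 CPM against 0.803 CPM in SH-SY5Y, its subclone. GI-ME-N had SRGN, a proteoglycan core protein, at 144 CPM against 0.125 CPM in IMR32, and SK-N-AS had EPHA3, an ephrin receptor, at 267 CPM against 0.620 CPM, beside PTPRC. NGP had FAM49A at 587 CPM against 10.6 CPM in CLB-GA. That gene lies at 2:16549459-16666331, beside MYCN at 2:15940564-15947007. LS had MYRFL at 12:69825304-69959097, at 38.4 CPM against 0.242 CPM in NGP, and LYZ at 12:69348341-69354234, both on the chromosome of MDM2, which lies at 12:68808176-68850686. SK-N-BE(2)C had TDRD1, a germ cell gene, at 66.4 CPM against 0.237 CPM in Lan-6, SK-N-FI had POU3F3, a neural transcription factor, at 48.6 CPM against 0.390 CPM, and IMR5-75 had PYY, a gut hormone, at 112 CPM against 2.18 CPM. Lan-6 had VIL1 (15.4 CPM), SK-N-DZ VEGFD (155 CPM), CLB-GA CCDC68 (123 CPM), SH-SY5Y MAOB (38.1 CPM) and IMR32 SLC22A15 (37.2 CPM). NBL-S had CXorf49 and CXorf49B at 33.8 CPM each, a pair with the same value that is uncertain, as reads of near-identical copies cannot be assigned.

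As a check of the known kinship, log2 CPM was correlated across 15919 genes for all 91 pairs of lines. Genes are not independent replicates, so no p-value is given. IMR5-75 and its parent IMR32 ranked 3 of 91 (r = 0.868), and 1804 genes were at least 4-fold apart between them. SH-SY5Y and its parent SK-N-SH ranked 49 of 91 (r = 0.780), and 2771 genes were at least 4-fold apart, above the median of 2664 over all pairs. That pair differed in cell state, with mesenchymal scores of -0.85 and 5.09, CD274 at 0.987 and 95.0 CPM, and HLA-C at 7.46 and 287 CPM.

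Lan-6, and to a smaller degree GI-ME-N, carried a trend with transcript composition. In Lan-6 the median log2 level over the 14-line median was -0.97 in the fifth of genes with the lowest GC content and 1.23 in the fifth with the highest, and Spearman's rho across 15794 genes was 0.524 with GC content and -0.349 with transcript length. Genes are not independent replicates here either. In GI-ME-N the medians were -0.29 and 0.18, and rho was 0.0954 with GC content and -0.186 with length. LS had a trend of the opposite direction, with medians of 0.21 and -0.29 and rho of -0.285 with GC content and 0.137 with length. Over the 3949 stable genes rho with GC content was 0.313 in GI-ME-N and -0.246 in LS. The scaling factors of GI-ME-N (0.677), Lan-6 (0.823) and SK-N-SH (0.846) were the lowest, and those of the other 11 libraries were at least 0.995.

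**Figure D4:**
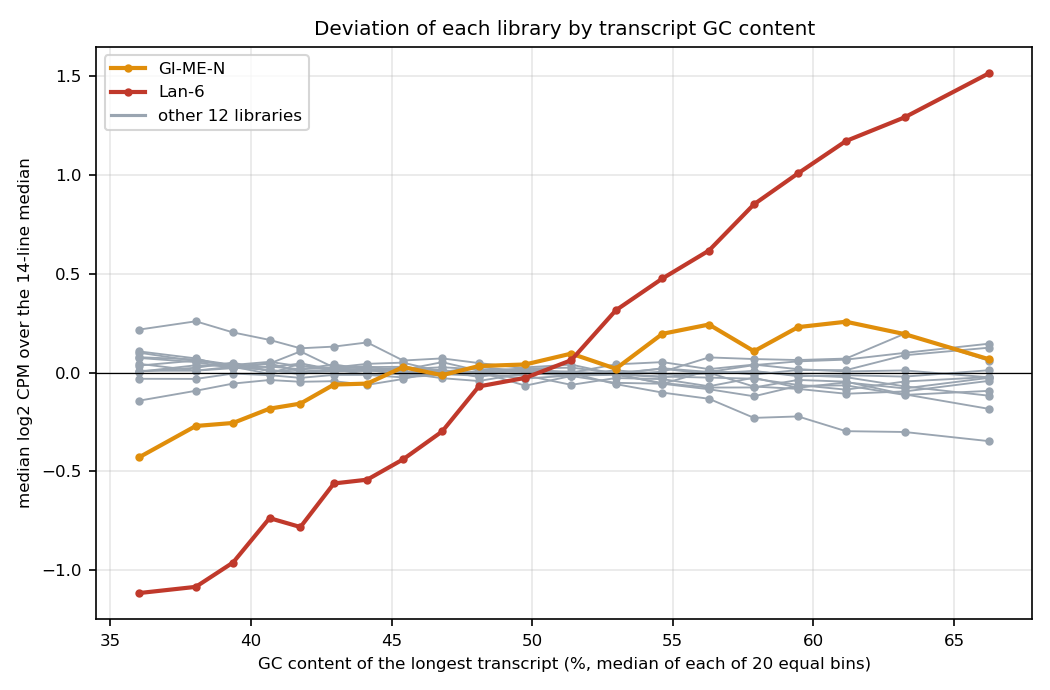
Median log2 CPM over the 14-line median (vertical axis) in 20 bins of transcript GC content (horizontal axis, percent), 1 line per library. Lan-6 rose across the bins, with medians of -0.97 and 1.23 in the fifth of genes with the lowest and the fifth with the highest GC content, and the other libraries stayed nearer to 0.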

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

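The omission of Lan-6 and GI-ME-N, the trend removal, the list without HLA genes and the mesenchymal covariate were chosen after seeing the data, and the other alternatives before. In all 22 alternatives MYCN with MYC, adrenergic with mesenchymal markers, and interferon-stimulated genes and CD274 with antigen presentation kept their direction and an adjusted permutation p under 0.05. Where others changed, the cause was not tested. With subclones in place of parents, r was 0.402 for mesenchymal markers and 0.383 for STING1 with antigen presentation and 0.620 for sensing with interferon-stimulated genes, each past the threshold no longer, while TERT and antigen presentation reached -0.679 (adjusted permutation p = 0.0396). Without the 2 farthest lines, r was 0.349 for mesenchymal markers and 0.342 for STING1 with antigen presentation, -0.468 for TERT and ATRX and -5.6e-04 for MYCN and TERT. Over all 14 lines MYCN and antigen presentation had -0.582 (adjusted permutation p = 0.0450). On the deposited stabilised values sensing and interferon-stimulated genes had 0.592, and MYCN and TERT -0.0126. With the trend removed the relations of sensing (0.638) and STING1 (0.590) were lost, without HLA genes that of mesenchymal markers (0.588), and without Lan-6 and GI-ME-N that of STING1 (0.592), while TERT and antigen presentation had -0.673 (adjusted permutation p = 0.0440). Adjusted permutation p over the alternatives of TERT and antigen presentation ran from 0.0396 to 0.475, and for MYCN and antigen presentation from 0.0383 to 0.438.

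Leaving out 1 line at a time, r ran from 0.436 to 0.734 for mesenchymal markers, 0.3999 to 0.832 for STING1, -0.716 to -0.472 for MYCN and -0.658 to -0.348 for TERT, each with antigen presentation. It ran from 0.594 to 0.802 for sensing with interferon-stimulated genes, -0.0709 to 0.234 for MYCN and TERT, -0.0269 to 0.630 for TERT and ATRX, and -0.426 to 0.0362 for TERT and sensing. The number of relations passing was 4 to 8, with 4 without IMR32, NBL-S, NGP, SK-N-AS, SK-N-DZ or SK-N-SH. Genes called in edgeR were 0 to 14 for antigen presentation, with 0 without SK-N-BE(2)C, CLB-GA, IMR32, Lan-6, LS, NGP, SK-N-DZ or SK-N-SH (1302 to 2365 at an unadjusted p under 0.05), 1 without SK-N-AS, 12 without GI-ME-N and 14 without SK-N-FI. They were 0 to 2 for TERT, with 2 without CLB-GA, and 0 to 1296 for MYCN. For MYCN the count was 0 without IMR32 (3387 at an unadjusted p under 0.05), 3 without NGP, 5 without SK-N-SH, 7 without GI-ME-N, 41 without SK-N-DZ, 117 without NBL-S, 287 without SK-N-BE(2)C, 298 without LS, 859 without Lan-6 and 1296 without SK-N-AS. Of the 554 genes, 508 kept their sign and an unadjusted p under 0.05 whichever line was left out, and all 6 of antigen presentation did. Both sets had been called on nearly the same lines at a stricter threshold, so this is no independent support.

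DESeq2 called more genes than edgeR's 6, 0 and 554: 1012 for antigen presentation, 297 for TERT and 2674 for MYCN. The antigen presentation scan called 0 in edgeR with subclones (1294 at an unadjusted p under 0.05), without SK-N-SH and CLB-GA, the 2 farthest lines (1163), and with the trend removed (2105), 0 in limma on stabilised values (2277), 1 with the mesenchymal covariate, and 15 without Lan-6 and GI-ME-N. The TERT scan called 1 over all 14 lines, 3 with no filter and 2 with the trend removed. The MYCN scan called 1151 over all 14 lines, 0 in edgeR with subclones (3395 at an unadjusted p under 0.05), 1256 without the 2 farthest lines, 125 without Lan-6 and GI-ME-N and 1 with the mesenchymal covariate, under which the slope of COL1A2 was 0.085. With subclones, 510 of the 554 genes kept their sign and an unadjusted p under 0.05 in edgeR, a looser threshold than that of their call. Of the other slopes of named genes none turned, and 248 of 546 values for MYCN and 76 of 115 for antigen presentation lost their adjusted p under 0.05. Line-specific genes numbered 632 at 4 times and 114 at 16 times the next line. The pair IMR5-75 and IMR32 ranked 1 over the 1000 most variable genes, 3 on the stabilised values and 5 by Spearman. SH-SY5Y and SK-N-SH ranked 48, 59 and 61 in the same order. DESeq2's size factors shifted the median log2 level by at most 0.07, in Lan-6. At 1 library per line, depth limits genes near 3 counts.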

Other observations

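Of the tests in this part, those of shared sequence and of GC content for the gene runs were set down before their results were seen, and those of the libraries that stand apart, the chance of long runs, the genes of low level inside them, the antigen presentation list and the random orders were chosen only after.

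In NGP and LS whole stretches of chromosome 12 were expressed above the other lines. In NGP, 28 consecutive genes from CAMKK2 to KMT5A (12:121237691-123409358, GRCh38) were each at least 4-fold over their 14-line median, with a median log2 ratio of 3.03. In the same line 9 genes from AGAP2 to SLC16A7 (12:57723761-59789855), with CDK4 among them, had a median of 2.88, and 8 genes from RAP1B to CCT2 (12:68610839-69601570), with MDM2 among them, a median of 3.02. In LS, 10 genes from NUP107 to KCNMB4 (12:68686734-70434292) had a median log2 ratio of 5.24, with CPSF6 at 15485 CPM, CCT2 at 14131 CPM and MDM2 at 4090 CPM. LS also had a run of 6 genes from PIP4K2C to OS9 (12:57591174-57721557), with B4GALNT1 among them. Further runs in LS held 4 genes each at 12:56998834-57213351 and 12:57768471-57846739, and 5 genes from PPP6R3 to IGHMBP2 (11:68460731-68940602). Around MYCN, IMR32 and its subclone IMR5-75 had the same run of 4 genes from FAM84A to MYCN (2:14632686-15947007), with medians of 5.02 and 5.15. In it FAM84A was at 2102 and 2557 CPM, DDX1 at 7796 and 6558 CPM, and MYCN at 1442 and 598 CPM. Lan-6 had 7 runs and GI-ME-N 2, and with the GC and length trend removed both had 0, so only those of NGP, LS, IMR32 and IMR5-75 are described here.

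For the 5 runs of at least 6 genes in NGP and LS, the tables argue against reads shared within a run for the median gene. That gene shared 0.674% of its 31-mers with another gene of its run. Some genes shared far more, among them ARL6IP4 (50.1%, the highest), CDK4 (37.98%) and TSPAN31 (25.96%) in NGP. For such genes the test does not argue against shared reads. Genes outside the run were not compared, so reads shared with genes elsewhere in the genome were not tested. The tables argue against a GC or length trend, since the longest runs were still 28 and 10 genes once it was removed. They also argue against chance, since 0 of 1000 shuffled gene orders reached 28 genes and the longest shuffled run had 5 genes. The tests of shared reads and of chance therefore do not cover the runs of 4 and 5 genes. The 15 genes inside the long runs that were too low to be used for finding them had a median log2 ratio of 3.45, and 14 were at least 2-fold up, as a raised copy number of whole segments would give. As a hypothesis, these longer runs may mark amplified DNA, which is well known for MYCN, MDM2 and CDK4 in neuroblastoma. No DNA copy number was analysed here, and the labels name no biological difference, so no biological explanation was tested.

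For Lan-6 and GI-ME-N, GC content and length accounted for 46.8% and 15.3% of the variance of the library over stable genes, against at most 2.08% in 6 reference libraries and 5.54% in LS, the highest of the 6 lines on which the stable genes were picked. They do not account for the whole difference, since after removal the SD of their log2 deviations was 0.872 in Lan-6 and 0.830 in GI-ME-N, with 0.708 as the highest reference (IMR5-75). A few genes taking most of the counts are argued against, since the 10 largest took 10.7% of counts in Lan-6 and 9.99% in GI-ME-N, below the 11.8% of IMR5-75. Mitochondrial genes took 11.7% of counts in IMR5-75, 9.77% in Lan-6 and 6.46% in GI-ME-N, so that comparison does not cover nuclear genes alone. A candidate explanation is a difference in RNA quality or library preparation, for which the labels give no batch or date. The cell state of GI-ME-N stays open beside it and was not tested.

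Antigen presentation genes were high or low together across lines. Misassigned reads of HLA alleles are argued against as the cause, since the score of the 5 HLA genes and that of the other 10 members had r = 0.923 over 12 lines (permutation p = 2.0e-05) and 0.926 without IMR32 and NBL-S. A GC or length trend is argued against only as the cause of the relation to interferon-stimulated genes, which had r = 0.842 with it removed (adjusted permutation p = 0.00192). Whether the members still went together with the trend removed was not tested. Neither test bears on why the lines differ, and no biological explanation was tested.

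When the levels were assigned to the lines in random order, the 6 genes called for antigen presentation were reached in 1 of 41 orders, the real one included, with 2 as the highest other. The 554 genes for MYCN were reached in 1 of 41, with 1 as the highest other. No random order of the same level thus reached either count. As 1 of 41 is the smallest share that so few orders can give, they argue against chance for both counts but do not exclude it. Any order reaches the 0 genes called for TERT (41 of 41), so these orders say nothing about chance there. The highest of the random orders for TERT gave 286 genes and the median order 0, so a random order can give a large count. Why that order did so was not tested.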
